A study of Oryzias latipes with 60 samples.

How the data were processed

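Poly-A RNA sequencing was carried out on whole juvenile medaka (Oryzias latipes), a small freshwater fish used as a vertebrate model, giving 60 libraries in 10 groups. Wild-type fish and fish transgenic for xmrk, the constitutively active relative of the epidermal growth factor receptor that drives pigment cell tumours in Xiphophorus hybrids, received cisplatin at 70 µM, trametinib at 20 nM, the vehicle of either drug (saline for cisplatin, DMSO for trametinib) or no treatment. Cisplatin is a platinum compound that crosslinks DNA, and trametinib is an inhibitor of the kinase MEK. Per the labels, drug and vehicle fish spent 5 days in petri dishes, while the untreated fish stayed in their ordinary housing, so each comparison of a vehicle with untreated fish contains the move to the dish as well as the vehicle. The fish were about 10 mm long, and RNA integrity numbers exceeded 8.0 per the labels. Each title carries a fish number that occurs once in the series, and each library was taken as 1 fish, which the labels do not state in words.

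The authors deposited a table of raw read counts per gene, whole numbers for 20459 Ensembl medaka genes in 60 columns, 1 per fish, and every column could be matched to a sample by its name. Per the submitters' processing notes, TopHat2, listed with version 2.2.4, and featureCounts were used. The genome build, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so counts of overlapping genes and of near-identical gene copies carry an uncertainty that could not be measured. The table names genes by Ensembl identifiers only. The reference table at hand lists symbols without these identifiers and 0 of the 20459 identifiers matched it, so genes are given by identifier, nothing is said about what they encode, and no position is given. For the same reason the 41 lists of genes fixed before the data were examined (0 of them with 5 or more matched members) could not be tested.

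Total counts per library ranged from 34788594 to 67018564 with a median of 51038009. Each library detected between 17788 and 19424 genes, and 186 genes had no read in any library. The 170 pairs of libraries within groups were compared by a chi-square of their counts over genes, and the smallest value, 45.94 per gene, was far above the sampling noise, so no library was counted as a duplicate of another.

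The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the groups of each fit, libraries were scaled with the TMM method, dispersions were estimated robustly, and contrasts were tested with the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are called, and this is the adjusted p given throughout. Standard errors of log2 fold changes were taken from the F statistic. In all, 5 separate fits were made: untreated fish (10 libraries), saline and cisplatin fish (25), DMSO and trametinib fish (25), untreated and saline fish (20), and untreated and DMSO fish (20). They gave 13 comparisons: transgenic against wild-type fish when untreated, in saline and in DMSO; each drug against its vehicle in either genotype; the difference of each drug response between genotypes; and each vehicle against untreated fish in either genotype. Levels are given as CPM scaled with the TMM factors of the fit, as mean ± SD over fish. Library measures (TMM factor, share of counts in the 10 most abundant genes, total) were compared between groups by 24 two-sided exact permutation tests of the difference of means, with Benjamini-Hochberg adjustment over the 24.

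The genes called in one comparison were tested as a set in another comparison that shares no library with it, with fry (a test of whether the genes move, on balance, in their first direction) and with camera (a test against all other genes, with a preset correlation of 0.01 and with an estimated one), both from limma 3.58.1 on log2 CPM with a prior count of 2. The set tests other than that of the untreated genotype genes under the drugs were added after the data were seen. Calls shared by comparisons without common libraries are set beside the number that independent lists would share, the product of the list sizes divided by the number of genes tested in both. The 4 vehicle comparisons share untreated fish, so their common calls were also counted with the untreated fish divided between saline and DMSO, and in 5 simulations of unchanged groups.

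The rule for naming genes, fixed before the data were examined, took the genes with the largest fold changes in each direction among called genes with an average log2 CPM of at least 1 and a symbol, together with members of the gene lists and a few genes of the epidermal growth factor receptor family and its signalling. As no gene had a symbol, only the first part was applied, without that condition and with at most 2 genes in each direction per comparison. Alternatives fixed before the data were examined were RLE scaling, no filter beyond 1 read, a filter of at least 1 CPM in at least 5 fish, DESeq2 1.42.0, limma-voom with sample quality weights, all 10 groups in a single fit, the compared groups alone, and leaving out each fish of the compared groups in turn. Other fish of a fit, which share its estimate of the spread, were not left out 1 at a time. Added after seeing the data were 2 surrogate variables from sva 3.50.0, leaving out the 6 libraries whose TMM factor over all libraries was under 0.8, both together, and leaving out each fish in turn in the set tests and shared calls. The only set tests repeated with a fish left out were those of the untreated genotype genes under the drugs in transgenic fish. Up to 100 splits of the compared libraries, the real one included, were refitted for each comparison.

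The fits were tested on simulated data with 200 genes changed by known factors. Genes were drawn independently of one another, and apart from the changed genes all libraries had the same composition. The recovered shares and false calls therefore do not cover genes that vary together or the differences of composition between the real libraries. For untreated transgenic against wild-type fish (18308 genes), 71% of the changes of 2-fold and 93% of those of 4-fold were recovered with 8 false calls. For cisplatin (18690 genes) the shares were 23% and 78% with 3 false calls in transgenic fish and 13% and 59% with 3 in wild-type fish. For trametinib (18706 genes) they were 46% and 89% with 4 false calls in transgenic fish and 34% and 81% with 4 in wild-type fish. For vehicle against untreated wild-type fish they were 31% and 87% with 5 false calls for saline (18632 genes), and 64% and 90% with 9 for DMSO (18623 genes). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.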

Results

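Whole-fish transcriptomes were measured by poly-A RNA sequencing in 60 juvenile medaka, 35 of them transgenic for xmrk and 25 wild type. The untreated, saline and DMSO groups held 5 fish of each genotype, and the cisplatin and trametinib groups held 10 transgenic and 5 wild-type fish each. Total counts per library lay between 34788594 and 67018564. Group means ran from 47842948 ± 5267283 (SD, n = 10) in transgenic trametinib fish to 54817790 ± 6906263 (SD, n = 5) in untreated transgenic fish. Genes are known by identifier only, so the reads of xmrk itself could not be looked up and the genotype labels were not checked against them. Nothing in the labels pairs fish across groups or gives a batch, and p-values measure the spread between the fish of a group, taken as independent. Which fish shared a dish is not known here, and the fish numbers of each group form a separate range. An effect of dish or handling can therefore not be told apart from the group, in the drug and genotype comparisons too.

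The libraries differed in composition. The TMM factor over all 60 libraries was under 0.8 in 6 fish. They were transgenic saline fish 17 (0.232), transgenic cisplatin fish 21 (0.292) and 31 (0.601), wild-type cisplatin fish 40 (0.685), transgenic trametinib fish 63 (0.774) and wild-type DMSO fish 47 (0.778). With counts scaled by library totals alone, in fish 17 the 200 genes most abundant over all libraries lay at a median log2 difference of 0.29 from the other fish of its group, and the remaining genes at -1.84. The factor was also lower in wild-type cisplatin fish (0.875 ± 0.111, SD, n = 5) than in wild-type saline fish (1.07 ± 0.0623, n = 5; two-sided exact permutation p = 0.00794, the smallest that 5 against 5 fish allow, adjusted p = 0.0318 over 24 tests). In the same fish the 10 most abundant genes took 16.4% ± 1.41 of the counts against 12.6% ± 1.03 (exact permutation p = 0.00794, adjusted p = 0.0318). Transgenic cisplatin and saline fish did not differ detectably in the factor (exact permutation p = 0.616, adjusted p = 0.87). Vehicle fish differed from untreated fish too, in 4 more of the 24 tests (each adjusted p = 0.0318). The factor was lower in wild-type saline fish than in untreated wild-type fish (1.17 ± 0.0145, n = 5). The share of the 10 most abundant genes was 10.1% ± 0.528 (n = 5) in untreated wild-type fish against 12.6% in saline and 12.9% ± 1.68 (n = 5) in DMSO, and 10.8% ± 0.588 (n = 5) in untreated transgenic fish against 13.1% ± 1.49 (n = 5) in saline.

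**Figure D1:**
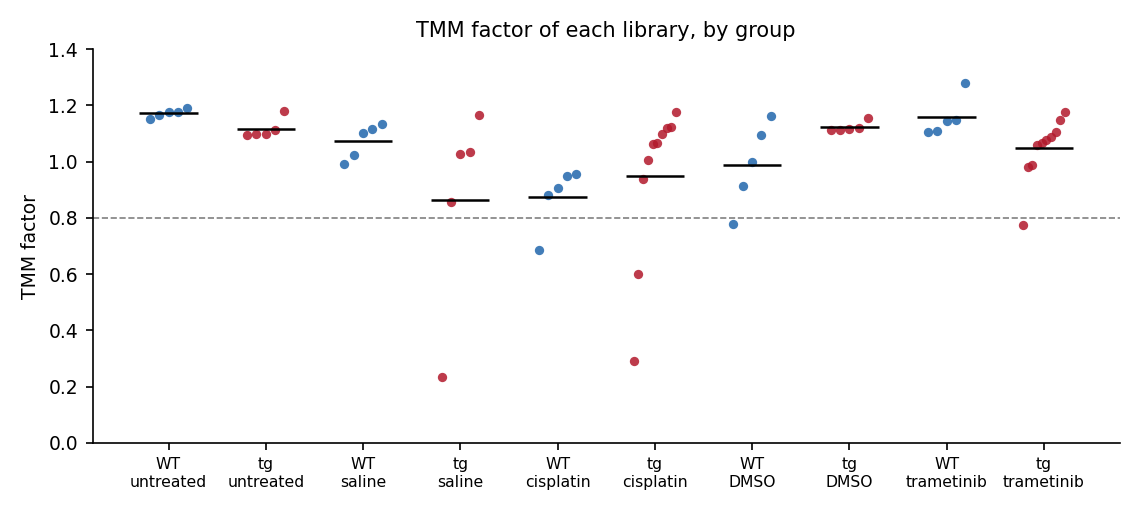
TMM factor (no unit) of each of the 60 libraries by group, with wild-type fish in blue, transgenic fish in red, black lines at the group means and a dashed line at 0.8. The 6 libraries under 0.8 fall in 5 of the 10 groups, and the lowest are transgenic saline fish 17 at 0.232 and transgenic cisplatin fish 21 at 0.292.

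A block of 363 genes varied together between fish of the same group. These genes were high in 27 fish and low in 33, with a median ratio of 16 between the means of the high and the low fish, and both states occurred in each of the 10 groups. ENSORLG00000007271, a member chosen after its values were seen, had a median of 49.1 CPM (range 17.4 to 963) in the 27 fish and 0.215 CPM (0.0396 to 9.47) in the other 33. None of the 363 genes was called in the 9 comparisons of genotype, drug or drug response by edgeR, with 0 to 24 of them at an unadjusted p under 0.05 per comparison, 0 to 3 called by DESeq2 and 0 to 2 by limma-voom. The genes were chosen for their variation within groups, which widens the spread that these tests use. The lack of calls therefore does not show that the block is unrelated to genotype or drug. In the vehicle comparisons 16 and 3 were called for saline against untreated transgenic and wild-type fish, and 7 and 6 for DMSO. DESeq2 called 39 and 4 for saline and 12 and 6 for DMSO, and limma-voom 8 and 19, and 14 and 8.

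**Figure D2:**
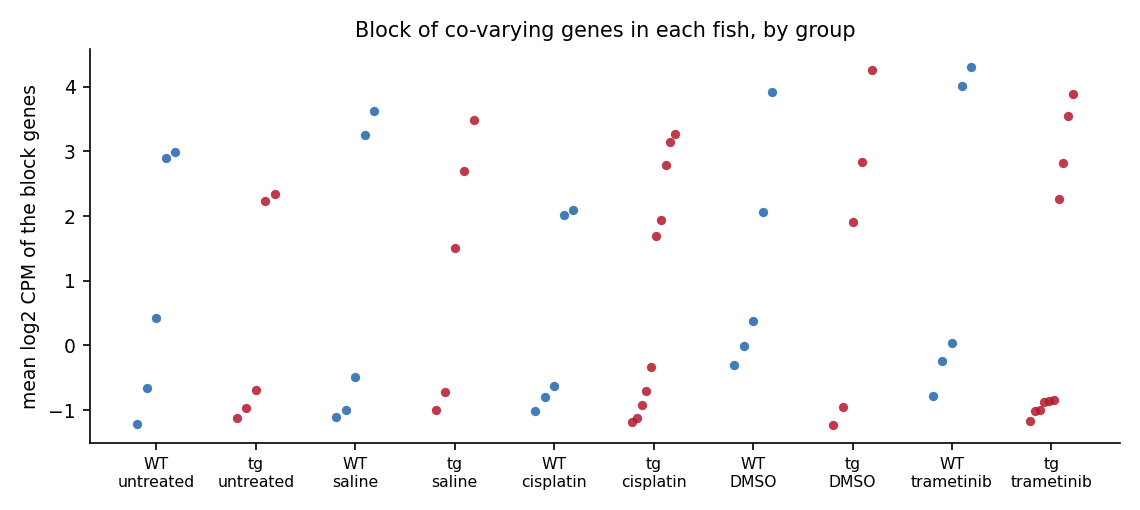
Mean log2 CPM over the 363 genes of the block in each fish by group, with wild-type fish in blue and transgenic fish in red. The 27 high fish lie at 1.5 or more and the 33 low fish at 0.419 or less, and each of the 10 groups holds both.

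Untreated transgenic fish were compared with untreated wild-type fish. No group separates the transgene from other genetic differences between transgenic and wild-type fish. ENSORLG00000000443 stood at 9.38 CPM ± 2.19 (SD, n = 5) in transgenic and 0.0433 CPM ± 0.0254 (n = 5) in wild-type fish, a log2 fold change of 7.68 (SE 0.31, adjusted p = 3.53e-07). ENSORLG00000019887 went the other way, with 0.045 CPM ± 0.0455 in transgenic and 13.9 CPM ± 2.5 in wild-type fish (log2 fold change -8.21, SE 0.41, adjusted p = 2.26e-06). For both genes all 5 fish of a genotype lay on one side of all 5 of the other. In total edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1450 of 18308 genes, 880 higher and 570 lower in transgenic fish, and 251 of them differed at least 2-fold. The count fell to 85 when all 10 groups shared a single fit, where the excess of higher calls turned (37 higher and 48 lower). It rose to 2756 with DESeq2 (1591 higher and 1165 lower), and lay between 800 (without wild-type fish 68) and 1590 when 1 fish was left out. ENSORLG00000000443 and ENSORLG00000019887 were called under every alternative, with log2 fold changes of 7.46 to 7.96 and -8.87 to -7.91.

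These genes followed genotype in the treated fish as well. Among the fish given a drug or vehicle, which had no part in the choice of the genes, ENSORLG00000019887 was under 1 CPM in 30 of 30 transgenic fish and at 1 CPM or more in 17 of 20 wild-type fish. ENSORLG00000000443 was at 1 CPM or more in 30 of 30 transgenic fish and in 3 of 20 wild-type fish. The exceptions were wild-type fish 41, 43 and 44 for the first gene and 35, 40 and 44 for the second. By the other 249 genes that were called in untreated fish and differed at least 2-fold, DMSO fish 44 lay with the wild-type fish. The score used, chosen after the data were seen, was the mean log2 CPM of the 147 genes higher in transgenic fish less that of the 102 lower. It was 0.27 in fish 44, at most 0.67 in any wild-type fish and at least 1.39 in any transgenic fish. No gene separated the genotypes without overlap over all 60 fish (0 of 18880 genes, and 0 in each of 20 shuffles of the genotype labels).

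**Figure D3:**
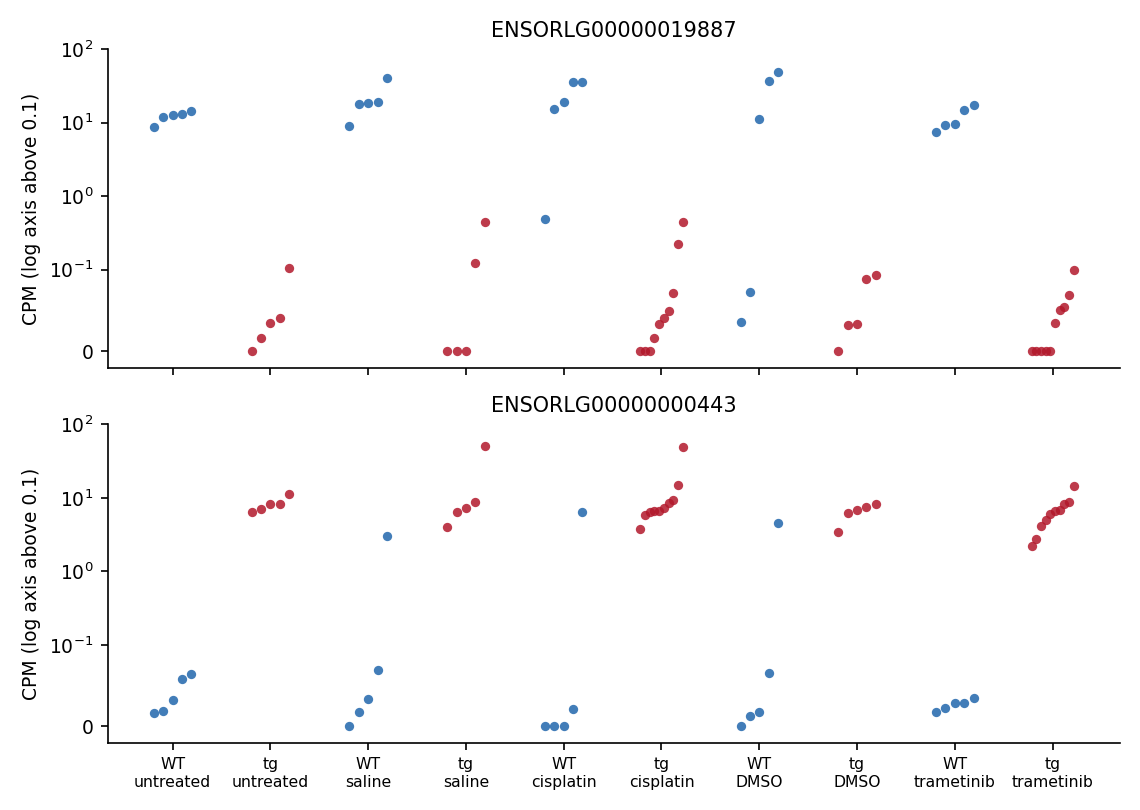
CPM of ENSORLG00000019887 and ENSORLG00000000443 in each of the 60 fish by group, on an axis that is linear near 0 and logarithmic above, with wild-type fish in blue and transgenic fish in red. Among fish given a drug or vehicle the first gene stays under 1 CPM in 30 of 30 transgenic fish, and the second reaches 1 CPM in 3 of 20 wild-type fish.

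Genotypes were also compared among fish kept in a dish with vehicle. The numbers of calls come from fits of different size, and their order depended on the fit: 1450 untreated, 52 in saline and 116 in DMSO with separate fits, and 85, 3739 and 95 with all 10 groups in a single fit. In saline, ENSORLG00000019887 had a log2 fold change of -8.54 (SE 1.28, adjusted p = 0.00287), from 18.7 CPM ± 10.4 (SD, n = 5) in wild-type fish to 0.102 ± 0.175 (n = 5) in transgenic fish, and in DMSO one of -8.58 (SE 1.39, adjusted p = 0.00439), from 20.7 ± 23.8 with a median of 12 to 0.0533 ± 0.0436. The largest rise in saline, ENSORLG00000019564 (log2 fold change 8.42, adjusted p = 0.0201), had transgenic fish 17 at 28.95 CPM against 0.0133 to 1.26 in the other 4 fish. Its log2 fold change was 4.86 without fish 17 (adjusted p = 0.0605) and 4.88 without all libraries of low TMM factor (adjusted p = 0.0111). The call was lost with limma-voom, with 2 surrogate variables and no libraries of low TMM factor, and without any 1 of wild-type fish 33 to 36, and with the saline groups alone the gene was filtered out. In untreated fish the gene was called as well (log2 fold change 5.97, adjusted p = 0.0229), but was removed by the filter of 1 CPM in 5 fish. In DMSO, ENSORLG00000000026 rose by a log2 fold change of 5.30 (SE 0.88, adjusted p = 0.00474), with transgenic fish 55 at 38.16 CPM and the other 4 between 1.07 and 3.61 against 0.232 ± 0.0612 (n = 5) in wild-type fish. The call of ENSORLG00000019887 was lost in saline with the compared groups alone and in DMSO with limma-voom (with the DMSO groups alone the gene was filtered out), and that of ENSORLG00000000026 under both settings. In saline 52 of 18690 genes were called, 21 higher and 31 lower. In DMSO they were 116 of 18706, 26 higher and 90 lower. The untreated comparison shared 26 calls of the same direction with saline (1.74 for independent lists) and 49 with DMSO (3.77), and saline and DMSO shared 21 (0.168). Of the 1450 untreated calls 71.1% had the same sign in saline (fry p = 3.62e-05, adjusted p = 0.000124 over 16 set tests) and 58.28% in DMSO (fry p = 0.051, adjusted p = 0.0742). In DMSO, camera p with an estimated correlation was 0.359 for the genes higher in transgenic fish and 0.0147 for those lower. In saline these were 0.0159 and 0.00405. Without the libraries of low TMM factor the share was 66.28% in DMSO (fry p = 0.0226, unadjusted) and 78.07% in saline (fry p = 1.62e-05, unadjusted). Whether the difference between genotypes changed from untreated to vehicle fish was not tested. The saline count ranged from 3 with the compared groups alone to 3739 with all 10 groups in a single fit, and was 2128 without the libraries of low TMM factor. The excess of lower calls was turned in the single fit (3190 higher and 549 lower) and without those libraries (1312 and 816). It was also turned with DESeq2 (425 and 192) and 2 surrogate variables (237 and 171). It remained with limma-voom (1620 and 1759) and with 2 surrogate variables and no libraries of low TMM factor (95 and 97). The DMSO count ranged from 39 with the compared groups alone to 360 with DESeq2.

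Cisplatin was compared with saline within each genotype. ENSORLG00000000284 was 5.54-fold higher under cisplatin in transgenic fish, at 5.71 CPM ± 1.97 (SD, n = 10) against 0.988 ± 0.5255 (n = 5; log2 fold change 2.47, SE 0.37, adjusted p = 0.00338), and 4.34-fold higher in wild-type fish, at 5.07 ± 1.39 (n = 5) against 1.17 ± 0.27 (n = 5; log2 fold change 2.12, SE 0.39, adjusted p = 0.0249). In both genotypes every cisplatin fish lay above every saline fish for this gene. ENSORLG00000009297 fell in both, from 132 ± 119 CPM to 6.62 ± 6.39 in transgenic fish (log2 fold change -4.32, SE 0.76, adjusted p = 0.00764) and from 193 ± 256 to 4.76 ± 1.81 in wild-type fish (log2 fold change -5.34, SE 1.05, adjusted p = 0.0439). In wild-type fish, leaving out 1 fish ended the call of the first gene for fish 34 to 39 and 42, and that of the second for fish 34 and 36 to 42. For the second gene saline fish 34 stood at 634.4 CPM against a group median of 74.56, and the log2 fold change was -4.12 without it. In wild-type fish ENSORLG00000002607 rose 3.28-fold, from 5.79 ± 0.587 to 19 ± 4.77 CPM (log2 fold change 1.72, SE 0.24, adjusted p = 0.00264), and ENSORLG00000003181 fell from 6.2 ± 5.85 to 0.239 ± 0.18 CPM (log2 fold change -4.67, SE 0.71, adjusted p = 0.00348). ENSORLG00000021053, the largest rise in transgenic fish (log2 fold change 6.32, SE 1.29, adjusted p = 0.0266), stood at 37.27 CPM in fish 21 and at 0.385 to 3.43 in the other 9 cisplatin fish, against 0.0569 ± 0.0868 (n = 5) in saline. It was not called with the compared groups alone or without any 1 of saline fish 14, 15, 16 and 17, and its log2 fold change fell to 4.72 without the libraries of low TMM factor.

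The test called 63 of 18690 genes for cisplatin in transgenic fish, 13 higher and 50 lower, and 14 in wild-type fish, 9 higher and 5 lower. The lists shared 6 genes of the same direction, against 0.0196 for independent lists. Both contrasts share the estimate of the spread of a single fit, so the lists are not fully independent even without a drug effect. Of the 63 genes 84.13% had the same sign in wild-type fish (fry p = 0.0014, adjusted p = 0.00373; camera p with an estimated correlation 0.00228 for the genes that rose and 0.018 for those that fell), and of the 14 genes 71.43% had the same sign in transgenic fish (fry p = 6.33e-08, adjusted p = 5.06e-07; camera p with an estimated correlation 0.0158 and 3.82e-05). By direction, 100% of the 5 wild-type falls were also lower in transgenic fish, but only 55.6% of the 9 rises were also higher. Among all genes 55.7% were higher, so the signs of the rises did not stand out. The transgenic count lay between 30 without saline fish 17 and 714 without cisplatin fish 21, and was 305 without the libraries of low TMM factor. The wild-type count lay between 6 and 16 when 1 wild-type fish was left out. Transgenic fish 17 and 21, which share the estimate of the spread, were not left out 1 at a time for it. With DESeq2 it was 258 (141 higher and 117 lower) and with 2 surrogate variables 548 (373 and 175). Without the libraries of low TMM factor it was 2259 (973 higher and 1286 lower), which turns the excess of higher calls. The excess also turned with the compared groups alone (2657, of them 931 higher and 1726 lower) and with limma-voom (4934, 2101 and 2833).

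Whether the response to cisplatin differed between genotypes was tested directly, and 1 gene passed (1806 at an unadjusted p under 0.05). ENSORLG00000009468 rose from 22.3 CPM ± 4.54 (SD, n = 5) to 59 ± 8.83 (n = 5) in wild-type fish and stood at 24 ± 6.56 (n = 5) and 15.9 ± 4.3 (n = 10) in saline and cisplatin transgenic fish (log2 difference of responses -2.00, SE 0.30, adjusted p = 0.0126). The call was lost with all 10 groups in a single fit, with 2 surrogate variables and no libraries of low TMM factor (log2 difference -1.39, adjusted p = 0.231), and without any 1 of wild-type fish 33, 35 and 41. The number of calls was 40 with DESeq2, 1922 without the libraries of low TMM factor and 4344 with limma-voom.

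Trametinib was compared with DMSO in the same way. ENSORLG00000005784 was 106-fold higher under trametinib in transgenic fish, at 1095 CPM ± 502 (SD, n = 10) against 10.3 ± 8.64 (n = 5; log2 fold change 6.73, SE 0.71, adjusted p = 6.27e-06), and stood at 1167 ± 818 (n = 5) against 5.25 ± 1.33 (n = 5) in wild-type fish. ENSORLG00000003566 was 219-fold higher in transgenic fish, at 204 ± 134 CPM against 0.938 ± 0.671 (log2 fold change 7.77, SE 1.06, adjusted p = 0.000252). ENSORLG00000000766 fell from 15.4 ± 4 to 0.659 ± 0.349 CPM (log2 fold change -4.54, SE 0.44, adjusted p = 2.32e-06) and ENSORLG00000013728 from 11.1 ± 7.37 to 0.204 ± 0.266 CPM (log2 fold change -5.76, SE 0.87, adjusted p = 0.000751). For these 4 genes every one of the 10 trametinib fish lay outside the range of the 5 DMSO fish. All 4 were called under every alternative. In wild-type fish ENSORLG00000020251 was 292-fold higher, at 14.7 ± 8.93 CPM (n = 5) against 0.0458 ± 0.0354 (n = 5; log2 fold change 8.19, SE 1.01, adjusted p = 6.68e-05), again under every alternative. The lower level of ENSORLG00000000443 in wild-type trametinib fish (log2 fold change -5.03, SE 1.27, adjusted p = 0.026) rested on DMSO fish 44 at 4.872 CPM, and without that fish the log2 fold change was 0.13.

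**Figure D4:**
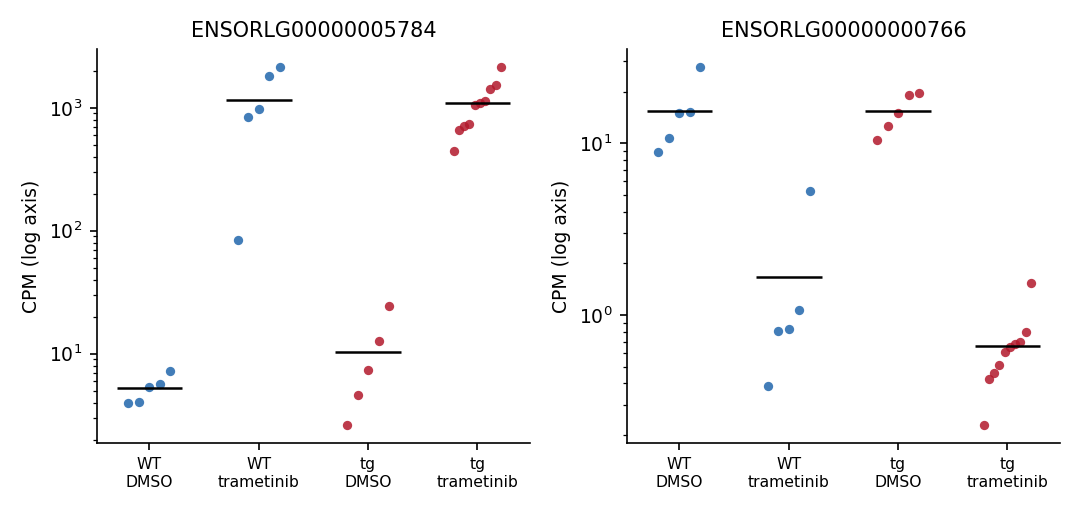
CPM (log axis) of ENSORLG00000005784 and ENSORLG00000000766 in each DMSO and trametinib fish, with wild-type fish in blue, transgenic fish in red and black lines at the group means. In transgenic fish the first gene goes from 10.3 to 1095 CPM and the second from 15.4 to 0.659 CPM.

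For trametinib 263 of 18706 genes were called in transgenic fish, 180 higher and 83 lower, and 979 in wild-type fish, 301 higher and 678 lower. The lists shared 91 genes of the same direction against 5.9 for independent lists, and 1 gene was called in opposite directions. Here too both contrasts share the estimate of the spread of a single fit. Of the 263 genes 83.65% had the same sign in wild-type fish (fry p = 3.86e-05, adjusted p = 0.000124; camera p with an estimated correlation 0.0261 for the genes that rose and 0.00185 for those that fell). Of the 979 genes 57.1% had the same sign in transgenic fish (fry p = 0.137, adjusted p = 0.169), but the directions differed. Of the 301 that rose 91% were also higher in transgenic trametinib fish (camera p with an estimated correlation 0.00497). Of the 678 that fell 42% were also lower (camera p with an estimated correlation 0.94). In transgenic fish 169 genes, 128 higher and 41 lower, were called in each of 10 alternative settings, and in wild-type fish 37, 28 higher and 9 lower. The transgenic count lay between 98 without DMSO fish 53 and 419 without trametinib fish 63. With limma-voom it was 3212, and the excess of higher calls turned (1530 higher and 1682 lower). With DESeq2 it was 753 (571 higher and 182 lower). The wild-type count was 47 with the compared groups alone (32 higher and 15 lower), 145 with 2 surrogate variables (89 and 56), 192 without DMSO fish 47 and 1831 with DESeq2.

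The difference of the trametinib response between genotypes gave 14 calls, all of them a higher response in transgenic fish (3727 genes at an unadjusted p under 0.05). ENSORLG00000004106 stood at 18.5 CPM ± 3.3 (SD, n = 5) in DMSO and 25.3 ± 5.65 (n = 10) in trametinib transgenic fish, and at 43.2 ± 24.7 (n = 5) and 13.5 ± 0.927 (n = 5) in wild-type fish (log2 difference 2.12, SE 0.37, adjusted p = 0.0462). ENSORLG00000007672 went from 34 ± 4.24 to 61.8 ± 10.7 in transgenic and from 69.4 ± 31.9 to 31.1 ± 11.5 in wild-type fish (log2 difference 2.02, SE 0.37, adjusted p = 0.0462). Each was called in 13 of 34 alternatives. The count was 0 with edgeR and 2 surrogate variables, 2 without the libraries of low TMM factor, 749 with DESeq2, and between 0 and 331 when 1 fish was left out.

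Whether the drugs moved the genes that differ between genotypes was examined with the 1450 untreated calls, whose libraries are in neither drug fit. Under cisplatin in transgenic fish 55.52% of them moved opposite to the difference between genotypes (fry p = 0.517, adjusted p = 0.517), and in wild-type fish 31.45% did (fry p = 0.00722, adjusted p = 0.0165; camera p with an estimated correlation 0.00858 for the genes higher in transgenic fish and 0.553 for those lower). Under trametinib 29.38% moved opposite in transgenic fish (fry p = 0.0142, adjusted p = 0.0252; camera p with an estimated correlation 0.0373 for the genes higher in transgenic fish and 0.176 for those lower) and 56.14% in wild-type fish (fry p = 0.293, adjusted p = 0.335). Tested on the differences of response between genotypes, 65.93% of these genes had a cisplatin response in transgenic fish that was shifted, relative to wild-type fish, opposite to the difference between genotypes (fry p = 0.0129, adjusted p = 0.0252; camera p with an estimated correlation 0.0241 for the genes higher in transgenic fish and 0.322 for those lower). For trametinib the share was 34% (fry p = 0.0192, adjusted p = 0.0307; camera p with an estimated correlation 0.0517 and 0.308). The shares in wild-type fish and for the differences of response come from the main fits only. Whether the lower TMM factors of wild-type cisplatin fish contributed to them was not tested. No gene was called by edgeR in the same direction for both drugs. Independent lists would share only 0.346 in transgenic and 0.325 in wild-type fish, so these counts decide little. With edgeR and 2 surrogate variables the numbers were 6 (2.42 for independent lists) and 0 (2.23), and without the libraries of low TMM factor 5 (3.62) and 8 (40.7). DESeq2 gave 7 (2.81) and 6 (10.5), and limma-voom 34 (48.5) and 20 (79.2). At an unadjusted p under 0.05 in both, 102 genes had the same direction in transgenic fish (105 for independent lists) and 27 in wild-type fish (218). Calls in opposite directions exceeded those of independent lists, with 3 (0.53) in transgenic and 2 (0.407) in wild-type fish by edgeR, 24 (5.24) and 29 (10.7) by DESeq2, and 114 (45.7) and 142 (72.7) by limma-voom. In wild-type fish the mean TMM factor also moved in opposite directions. It was 0.875 under cisplatin against 1.07 in saline, and 1.16 under trametinib against 0.989 in DMSO (exact permutation tests, adjusted p = 0.0318 and 0.171). Whether this contributed was not tested. Without transgenic cisplatin fish 21 the edgeR number of the same direction was 2, and without wild-type cisplatin fish 39 it was 1 in wild-type fish.

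Vehicle fish in dishes were compared with untreated fish in their ordinary housing, so vehicle and housing changed together. ENSORLG00000010103 was 96.5-fold higher in wild-type saline fish, at 36.5 CPM ± 11.8 (SD, n = 5) against 0.377 ± 0.144 (n = 5; log2 fold change 6.59, SE 0.54, adjusted p = 4.16e-07), and 94.4-fold higher in wild-type DMSO fish, at 38.7 ± 10.9 against 0.409 ± 0.158 (log2 fold change 6.56, SE 0.43, adjusted p = 3.11e-09). In transgenic fish ENSORLG00000001198 was 133-fold higher in saline, at 127 ± 113 CPM against 0.953 ± 0.436 (log2 fold change 7.05, SE 0.70, adjusted p = 2.54e-06). Fish 17 stood at 325.9 CPM, and without the libraries of low TMM factor, of which it is the only one among these fish, the log2 fold change was 6.32. ENSORLG00000020069 fell from 694 ± 153 to 11.6 ± 2.1 CPM (log2 fold change -5.90, SE 0.49, adjusted p = 2.99e-07). In DMSO ENSORLG00000003912 was 46.3-fold higher, at 48.3 ± 44.6 CPM against 1.04 ± 0.465 (log2 fold change 5.53, SE 0.77, adjusted p = 3.44e-05), and ENSORLG00000013460 fell from 3.91 ± 1.39 to 0.147 ± 0.069 CPM (log2 fold change -4.72, SE 0.55, adjusted p = 3.27e-06). These 5 genes were called in these comparisons under every alternative. ENSORLG00000019801, with 0.0129 ± 0.0211 CPM in untreated wild-type fish, stood at 35.5 ± 33.3 in saline (adjusted p = 0.00921) and at 47.8 ± 45.9 in DMSO (adjusted p = 0.00155). ENSORLG00000014726 went the other way, from 2.11 ± 3.79 CPM, with untreated fish 70 far above the others, to 0.0137 ± 0.0306 in saline (adjusted p = 0.0188) and from 2.28 ± 4.09 to 0.0545 ± 0.104 in DMSO (adjusted p = 0.0398), and both calls were lost without fish 70 and with limma-voom. The saline call was also lost without saline fish 33, and the DMSO call without any 1 of DMSO fish 43, 44, 45 and 47 and without the libraries of low TMM factor.

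Between saline and untreated fish 5464 of 18632 genes were called in transgenic fish, 3363 higher and 2101 lower, and 2539 in wild-type fish, 1267 higher and 1272 lower. Between DMSO and untreated fish 4864 of 18623 genes were called in transgenic fish, 2161 higher and 2703 lower, and 7145 in wild-type fish, 3934 higher and 3211 lower. Called in the same direction in each of 10 alternative settings were 1055 and 1866 genes for saline, and 1990 and 3050 for DMSO. Of the genes called higher in transgenic saline fish, 70 had a lower level without the libraries of low TMM factor, 45 with 2 surrogate variables, 185 with both and 106 with limma-voom. The excess of higher over lower calls in these fish was also turned by the setting, to 3264 higher and 3748 lower without the libraries of low TMM factor, 3692 and 3989 with 2 surrogate variables, 3188 and 4223 with both, and 3543 and 3651 with limma-voom. For DMSO in wild-type fish it was turned with both, to 3573 higher and 3865 lower. Between comparisons without common fish, 3697 calls of the same direction were shared by saline in transgenic and DMSO in wild-type fish (1070 for independent lists, 12 in opposite directions), and 1953 by DMSO in transgenic and saline in wild-type fish (332, and 1 opposite). In all 4 comparisons 660 genes were higher and 711 lower among 18583 tested in each. Independent lists would share 5.59 and 3.61. In 5 simulations with no changed gene, whose untreated fish were simulated and shared by the comparisons, the numbers were 0 and 0. As nothing changed in them, they cannot show how far the shared untreated fish raise the observed numbers. With the untreated fish divided between saline and DMSO the numbers were 33 and 62 in one division and 143 and 234 in the other. Each comparison then held only 2 or 3 untreated fish per genotype. The fall therefore mixes the loss of fish with the end of sharing, and cannot show the part due to either. The saline count was 1110 in transgenic and 7660 in wild-type fish with the compared groups alone, and the DMSO counts were 2057 and 3439 with all 10 groups in a single fit.

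**Figure D5:**
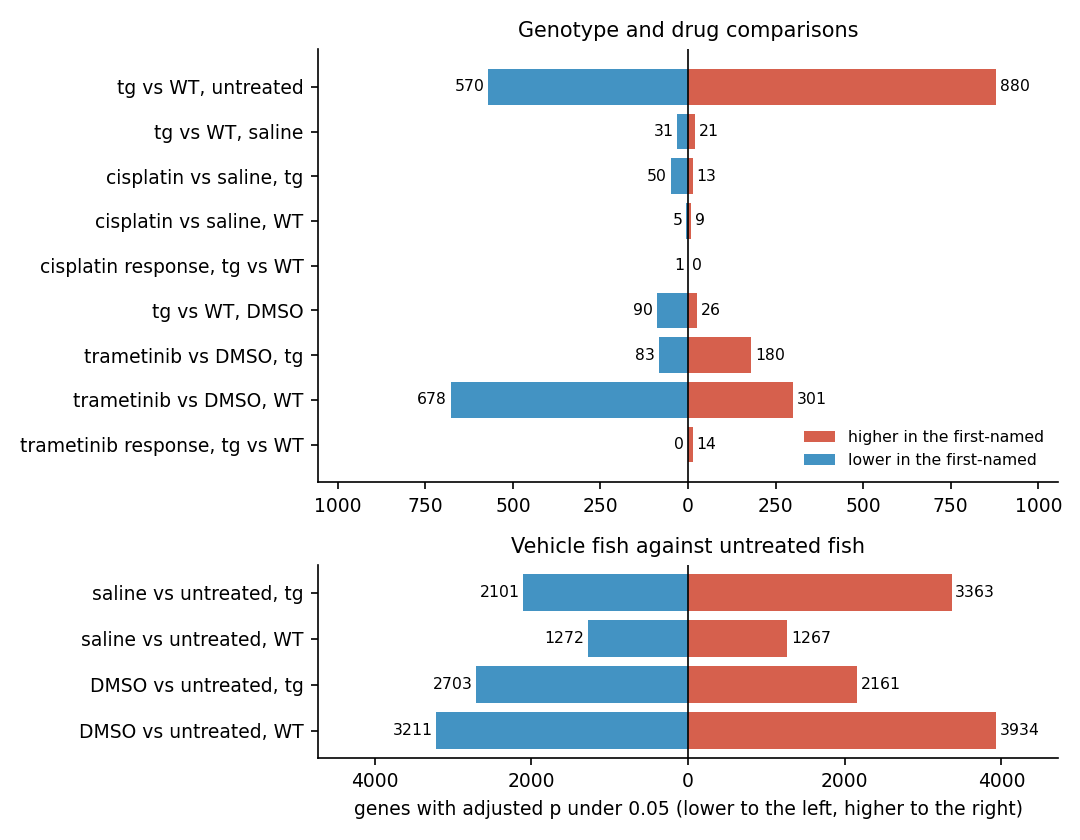
Number of genes called in each of the 13 comparisons, with genes lower in the first-named group to the left in blue and genes higher to the right in red, on separate scales for the vehicle comparisons. The vehicle comparisons call 2539 to 7145 genes, and the comparisons of genotype, drug and drug response 1 to 1450.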

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

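The tests of the block against genotype and treatment, of low TMM factors against the drugs and library by library, and of the vehicle comparisons against low TMM factors and batches were chosen after the results were seen.

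Within groups of 5 to 10 fish, 21 of 110 sets of values had an extreme fish set apart from the rest by a gap large against the range (Dixon's criterion at the 95% level), where chance alone picks about 5%. That rate is no measure for the 21, as most sets were levels of genes named for their large changes, and some repeated the same fish in 2 fits. Fish 17 of transgenic saline was extreme in genes detected (17788), and in the levels of ENSORLG00000019564 (28.95 CPM), ENSORLG00000019887 (0.4035 CPM) and ENSORLG00000001198 (325.9 CPM). Fish 21 of transgenic cisplatin was extreme in genes detected (17959) and in ENSORLG00000021053 (37.27 CPM), a gene for which transgenic saline fish 18 also stood apart (0.208 CPM). The TMM factor set apart untreated transgenic fish 73 (1.18), wild-type cisplatin fish 40 (0.6854), transgenic DMSO fish 57 (1.154), wild-type trametinib fish 48 (1.28) and transgenic trametinib fish 63 (0.774). Single genes set apart transgenic DMSO fish 55 (ENSORLG00000000026, 38.16 CPM), transgenic cisplatin fish 31 (ENSORLG00000009297, 23.62 CPM) and transgenic trametinib fish 60 (ENSORLG00000000766, 1.538 CPM). Wild-type DMSO fish 44 was extreme in ENSORLG00000000443 (4.872 CPM) and ENSORLG00000019801 (126.7 CPM), and ENSORLG00000014726 set apart wild-type DMSO fish 46 (0.239 CPM), wild-type saline fish 36 (0.06845 CPM) and untreated wild-type fish 70 (9.546 CPM in the fit with DMSO, 8.843 in the fit with saline). The responses of the genotypes differed in 1 gene for cisplatin and in 14 genes for trametinib by the test of the difference itself. For either drug 0 of these genes were called in each of 9 alternative settings. Leaving out 1 fish moved the trametinib count beyond 1.5 times in 24 of 25 fits.

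Of the 60 libraries 6 had a TMM factor under 0.8. Whether the drugs contributed stays open, as 4 of 30 drug and 2 of 20 vehicle fish are too few to decide (Fisher's exact p = 1), and wild-type cisplatin fish had lower factors than saline fish (adjusted p = 0.0318). A few genes taking most of the counts is argued against for 5 of the 6, whose factors stayed at or under 0.791 without the 10 most abundant genes of each library. For wild-type DMSO fish 47 it stays open, since its factor rose to 0.809, so that 5 of the 6 were still under 0.8. Shallower sequencing may contribute, as the mean rank of the 6 in total count was 16.5 of 60 and a share of 0.0188 of random sets of 6 ranked as low, but not alone, since the shallowest library (wild-type saline fish 34) had a factor of 1.134 and fish 40 and 63 ranked 39 and 32; no biological explanation other than the drugs was tested.

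The block of 363 genes was high in 27 fish and low in 33, in each group. Genotype and treatment are the same for all fish of a group, so neither alone sets the state, which follows from how the block was found and is no separate test. Whether they alter how often the block is high stays open, with 17 of 35 transgenic and 10 of 25 wild-type fish high (Fisher's exact p = 0.602) and a permutation p of 0.985 over the 5 treatments. Depth is argued against because 13 of the 30 shallower and 14 of the 30 deeper libraries were high (Fisher's exact p = 1) and totals from 34788594 to 67018564 cannot give a median ratio of 16. Sex of the fish is a candidate explanation that the data leave open: 27 of 60 did not differ detectably from an even division (exact binomial p = 0.519), but the labels give no sex and no gene of the ovary could be looked up by name.

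Vehicle fish differed from untreated fish in 2539 to 7145 genes. Libraries of low TMM factor are argued against as the cause, since without them the smallest of the 4 counts was 5812. Sequencing depth is argued against as well, as the mean totals of the 20 vehicle and 10 untreated fish differed by 0.0718% (permutation p = 0.991). A batch of fish or libraries cannot be told apart from the vehicle and the dish, as the labels give 0 batches that hold both kinds of fish. The move to a dish, the vehicle and such a batch could each account for the difference.

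Each comparison was refitted on up to 100 splits of its fish, the real one included. For most comparisons a share under 0.05 of the splits, the real one included, called as many genes as the real one. That argues against chance, but so few splits cannot exclude it. The number of such splits, the real count and the highest other count follow in that order. It held for genotype in untreated (1, 1450 and 210), saline (2, 52 and 158) and DMSO fish (1, 116 and 2). It also held for cisplatin in wild-type fish (1, 14 and 2). For trametinib it held in transgenic (2, 263 and 369) and wild-type fish (1, 979 and 364). The same held for saline in transgenic (1, 5464 and 1647) and wild-type fish (1, 2539 and 1), and for DMSO in transgenic (1, 4864 and 630) and wild-type fish (1, 7145 and 1193). For the differences of response to cisplatin (4, 1 and 968) and trametinib (2, 14 and 101) the splits cannot decide. They exchanged genotypes among the fish of each treatment, which removes every difference between genotypes and not the difference of response alone. The shares of splits were not adjusted for the 13 comparisons, and that for the difference of response to cisplatin, of a single gene, was the nearest to 0.05. For cisplatin in transgenic fish the splits did not argue against chance, with 12 of 100 calling at least the real 63 genes and the highest other 9000. Such counts point to a structure of these samples: fish 17 and 21, of low TMM factor, were in the same arm in 49 splits, 11 of which called at least 63 genes, while among the 51 splits with them apart only the real one did, and the highest other count there was 7. The highest other counts for the saline comparison of genotypes and for both differences of response were several times the real ones. A structure of the samples may lie behind them too, but which fish gave rise to them was not tested.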

How the results depend on the processing

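Chosen after seeing the data were the fits with 2 surrogate variables, without the 6 libraries of low TMM factor and with both, limma-voom for the calls shared by the drugs, and leaving out 1 fish in the set tests and shared calls. No paired analysis was possible because no fish number occurs in more than 1 group. The gene list tests, with their alternatives of an estimated correlation, fry and RLE scaling, were not run, as no gene had a symbol.

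RLE scaling, no filter and a filter of 1 CPM in 5 fish kept every count of called genes within 1.5 times its value. The other settings moved counts beyond that, and the cause was not tested. With all 10 groups in a single fit the counts were 85 for genotype in untreated fish and 3739 in saline, 413 and 43 for cisplatin in transgenic and wild-type fish, 462 for trametinib in wild-type fish, 0 and 24 for the differences of response to cisplatin and trametinib, and 2057 and 3439 for DMSO against untreated transgenic and wild-type fish. With DESeq2 they were 2756, 617 and 360 for genotype in untreated, saline and DMSO fish, 195 and 258 for cisplatin, 753 and 1831 for trametinib, and 40 and 749 for the differences. With limma-voom they were 3379 and 265 for genotype in saline and DMSO, 548 and 4934 for cisplatin, 3212 and 580 for trametinib, 4344 and 35 for the differences, and 8295 for saline against untreated wild-type fish. With the compared groups alone they were 3 and 39 for genotype in saline and DMSO, and 14 and 2657 for cisplatin. They were 463 and 47 for trametinib, and 1110 and 7660 for saline against untreated transgenic and wild-type fish. Fewer fish then estimate the spread, but 2657, 463 and 7660 lay above the main counts of 14, 263 and 2539. The wild-type fits of cisplatin and saline also lacked transgenic fish 17, of low TMM factor. With 2 surrogate variables the counts were 408 for genotype in saline, 281 and 548 for cisplatin, and 145 for trametinib in wild-type fish. They were 30 and 0 for the differences, and 7362 for saline against untreated wild-type fish. Without the libraries of low TMM factor they were 2128 and 75 for genotype in saline and DMSO, 305 and 2259 for cisplatin, 561 and 651 for trametinib, 1922 and 2 for the differences, and 6950 for saline against untreated wild-type fish. With both they were 192 for genotype in saline, 161 and 226 for cisplatin, 505 for trametinib in transgenic fish, 0 and 48 for the differences, and 8266 for saline against untreated wild-type fish. For each count of 0 the tool was edgeR, with 1806 genes (cisplatin) and 3727 genes (trametinib) at an unadjusted p under 0.05 in the fit of all fish.

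Calls shared by the drugs in transgenic fish numbered 7 with DESeq2 (2.81 for independent lists), 34 with limma-voom (48.5), 6 with 2 surrogate variables (2.42) and 5 without the libraries of low TMM factor (3.62). In wild-type fish they numbered 6 with DESeq2 (10.5), 20 with limma-voom (79.2) and 8 without those libraries (40.7). The share of untreated genotype genes moving opposite to the genotype difference reversed in the wild-type contrast, to 31.45% for cisplatin and 56.14% for trametinib. In the other settings, fitted for transgenic fish only, it lay between 54.58% and 60.14% for cisplatin and between 28.9% and 40.24% for trametinib.

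Leaving out 1 fish gave 800 to 1590 calls for genotype in untreated fish (beyond 1.5 times without wild-type fish 68, 69 and 71 or transgenic fish 74, at 800, 910, 823 and 826). In saline it gave 18 to 57 (wild-type fish 33 to 36, at 20, 18, 31 and 28, and transgenic fish 14, 16 and 18, at 30, 27 and 31), and in DMSO 39 to 164 (transgenic fish 53 to 57, at 47, 52, 39, 63 and 62, and wild-type fish 46 and 47, at 51 and 54). For cisplatin in transgenic fish it gave 30 to 714 (saline fish 16 and 17, at 33 and 30, and cisplatin fish 20, 21, 22, 24, 25, 26 and 32, at 39, 714, 33, 36, 38, 35 and 41), in wild-type fish 6 to 16 (saline fish 34 to 36, at 8, 9 and 6, and cisplatin fish 38, 39, 41 and 42, at 7, 9, 8 and 7), and for the difference 0 to 3 (0 without wild-type fish 33, 35 or 41, 2 without 34, and 3 without transgenic fish 15 or 31). For trametinib in transgenic fish it gave 98 to 419 (DMSO fish 53 to 57, at 98, 101, 118, 165 and 116, and trametinib fish 63, 65 and 67, at 419, 143 and 148), and in wild-type fish 192 to 1404 (DMSO fish 46 and 47, at 211 and 192, and trametinib fish 48 to 51, at 339, 212, 510 and 377). For the difference it gave 0 to 331: 0 without any 1 of fish 45 to 48, 53 to 57, 59, 61, 62 and 64 to 67, 1 without 49 or 52, 6 without 60, 7 without 50, 84 without 51, 100 without 58, 280 without 44 and 331 without 43. Saline against untreated fish gave 4227 to 7012 in transgenic and 1803 to 2070 in wild-type fish, and DMSO 4122 to 4782 and 6271 to 7581. The genotype gene shares in transgenic fish lay between 51.59% and 57.59% for cisplatin and between 27.52% and 32.14% for trametinib. The shared calls lay between 0 and 2 in transgenic fish (2 without cisplatin fish 21) and between 0 and 1 in wild-type fish (1 without cisplatin fish 39).

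Of 32 pairs of a named gene and a comparison, 18 were called under every alternative and 14 lost the call under at least 1, and 1 changed sign. The log2 fold change of ENSORLG00000000443 for trametinib in wild-type fish lay between -5.35 and 0.13 when 1 fish was left out, and reversed, to 0.13, without DMSO fish 44. Single fish also carried part of the size of other changes, with fold changes that shrank by a factor of more than 1.5 without them (log2 values follow). These were ENSORLG00000000026 (5.30 to 3.14 without transgenic DMSO fish 55), ENSORLG00000019564 (8.42 to 4.86, transgenic saline fish 17), ENSORLG00000021053 (6.32 to 4.79, transgenic cisplatin fish 21) and ENSORLG00000001198 (7.05 to 6.32, transgenic saline fish 17). With a wild-type fish left out they were ENSORLG00000009297 (-5.34 to -4.12, saline fish 34), ENSORLG00000003181 (-4.67 to -3.96, saline fish 34), ENSORLG00000019887 in DMSO (-8.58 to -7.91, fish 46), ENSORLG00000019801 in saline (11.11 to 10.45, fish 34) and DMSO (11.42 to 10.65, fish 44), and ENSORLG00000014726 in saline (-7.02 to -4.73) and DMSO (-5.42 to -3.14), both without untreated fish 70. Depth limits the fold changes of genes with few reads in a group, such as ENSORLG00000019801 and ENSORLG00000014726 with 4 reads over the 5 untreated and 5 saline wild-type fish, respectively.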

Other observations

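The tests of the genes of one drug under the other were chosen after the data were seen. Of the 63 genes called for cisplatin in transgenic fish 74.6% had the opposite sign under trametinib in transgenic fish (fry p = 0.0641, adjusted p = 0.0855 over 16 set tests), and of the genes called for trametinib 58.69% had the opposite sign under cisplatin (fry p = 0.44, adjusted p = 0.469). Calls for cisplatin in transgenic fish and for genotype in untreated fish coincided in direction in 3 genes (2.1 for independent lists) and were opposite in 9 (2.73). Calls for trametinib in transgenic fish coincided with those for genotype in 25 genes (10.9), 23 of them higher in both (8.37), and were opposite in 8 (9.37).

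In the vehicle comparisons 221 genes were at least 2-fold higher and 218 at least 2-fold lower in each of the 4. Without the libraries of low TMM factor 1425 genes were higher and 1908 lower in all 4, among them 650 of the 660 and 702 of the 711 found with all fish. Called in opposite directions in at least 2 of the 4 comparisons were 52 genes.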
